A study of Mus musculus with 25 samples.

How the data were processed

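RNA was sequenced from Achilles tendons of mice aged 3 months, in 25 libraries. Per the labels, the animals were wild type or AMPKcKO, a conditional knock-out written cKO here. They had cage activity or ran on wheels, and they were female or male. The series title names loss of AMPKα1, the catalytic subunit encoded by Prkaa1. Per the submitters' extraction notes, pulverised tissue went through TRIzol, a spin column and DNase on the column before library preparation. Per the submitters' processing notes, cutadapt 2.3, FastQC 0.11.8, STAR 2.7.8a and RSEM 1.3.3 were used with the mouse genome GRCm38 (mm10), and those notes give no role for each tool. The strand of the libraries and the release of the gene annotation are not stated. Gene positions were therefore read from a GENCODE annotation of GRCm38.

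The deposited expected counts are RSEM gene-level values, which were whole numbers for every gene and library in the file. The deposited FPKM values are in a separate table of the same 25 libraries. Both tables hold 55487 genes and 4 added entries for reporter sequences (Cre, eGFP, mCherry and tdTomato). The counts were used for every main value and the FPKM table for an alternative. Library names carry 2 project prefixes, and 2 libraries (WT cage female replicate 4 and cKO cage male replicate 3) carry the less common one.

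Counts were analysed in R 4.3.3 with edgeR 4.0.16. The 4 reporter entries were left out of the gene tests. Genes were kept by filterByExpr on the 4 groups of genotype and activity, which left 19155. Libraries were scaled by TMM, and a negative binomial model with the 4 group means and a sex term was tested with quasi-likelihood F-tests. The 10 comparisons were cKO against WT at cage activity, in runners and as the mean of both, running against cage in WT, in cKO and as the mean of both, the genotype-by-running interaction, male against female, and the interactions of sex with genotype and with running. The 2 interactions with sex used 8 group means. P-values are two-sided and were adjusted by Benjamini-Hochberg over the genes of each comparison, and a gene was called at an adjusted p under 0.05. Standard errors are those of the log2 fold change, and CPM are edgeR's library-scaled counts, with TMM factors for genes and without them for Cre and eGFP.

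Before the data were examined, 47 gene lists for tendon, metabolism, signalling and the cell types such a sample can hold were fixed, and 44 of them had at least 5 tested genes. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. Camera asks whether the genes of a list move relative to other genes. Fry asks whether they move one way on balance or, in its mixed form, in either direction. List p-values were adjusted over the 44 lists of a comparison, and gene p-values were also adjusted over the list alone. The rule for the genes named in the text was fixed in advance as well. It takes Prkaa1 and Prkaa2, up to 8 higher and 8 lower called genes with the smallest p and a mean log2 CPM of at least 1, or 3 in each direction where none was called, up to 4 members of each called list, and up to 3 members of the AMPK, tenocyte, fibrillar collagen and circadian clock lists. Predicted genes were left out, as were sex-linked genes outside the sex comparison. Any gene outside the rule is said to be chosen after its values were seen. For genotype at cage activity, 1 gene that the rule names is not reported here.

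Totals were 13193228 to 45724243 counts per library, with a median of 24538109. A count of 0 allows a level of up to 3 counts in that library's total. Such floors cover counting error alone. The muscle share is the percentage of a library's counts in 2 lists of skeletal muscle fibre genes, and 4 differences in it were tested by exact permutation of the libraries, two-sided. The muscle covariate used in alternative fits is the centred mean log2 CPM of the same genes. On simulated counts with the same group sizes, 100 genes changed 2-fold and 100 changed 4-fold in each comparison. Of the 2-fold genes, edgeR found 80 for the running mean, 58 and 61 for genotype at cage activity and in runners, and 33 for the genotype-by-running interaction. Of the 4-fold genes, it found 99, 96, 92 and 80. The simulated genes were independent of each other, which real genes are not.

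Alternatives covered RLE scaling, no filter or a stricter one of 1 CPM in 6 libraries, DESeq2 1.42.0, limma-voom with quality weights for the libraries (the setting behind every limma-voom count), limma on log2 FPKM with 1 or 0.1 added, a muscle covariate, the library project, a replicate block, the sex term, subsets of libraries and each library left out in turn. After the data had been seen, 5 more were added, namely an eGFP covariate, a mitochondrial rRNA covariate, and fits without the libraries with eGFP, without 2 libraries whose reporter counts stand against their group, and without 2 libraries low in muscle RNA.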

Results

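Transcripts were counted in whole Achilles tendons of 25 mice. The WT cage group held 7 libraries (4 female and 3 male), and the WT running, cKO cage and cKO running groups held 6 each (3 of each sex). The design asks what loss of AMPKα1, the catalytic subunit of the energy-sensing kinase AMPK encoded by Prkaa1, does to the tendon at cage activity and under wheel running. Totals ran from 13193228 counts in WT cage female replicate 4 to 45724243 in WT cage female replicate 1. The first principal component of log2 CPM took 16.6% of the variance and the second took 11.8%. On the second, WT running female replicate 2 lay at 112 and WT running male replicate 3 at 83.1, and every other library between -26.8 and 7.63. WT running female replicate 2 also had the fewest genes with a count (20006). Both belong to the WT running group of 6, and the cause was not tested. The most similar pair of libraries, cKO cage male replicate 1 and WT cage male replicate 1, had r = 0.978 across genes, which are not independent replicates.

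The gene targeted in the cKO, Prkaa1 (ENSMUSG00000050697, chromosome 15, 5143861 to 5181899, GRCm38), was counted in every library. In WT cage females it stood at 27.5, 19.5, 31.1 and 13.4 CPM, and in WT cage males at 19.7, 23.1 and 26.2 CPM. In WT running females it stood at 20.5, 31.1 and 15.6 CPM, and in WT running males at 17.8, 26.3 and 27.1 CPM. In cKO cage females it stood at 16.3, 13.9 and 17.6 CPM, and in cKO cage males at 21.2, 18 and 18.1 CPM. In cKO running females it stood at 18.7, 16.4 and 16.2 CPM, and in cKO running males at 19.0, 18.6 and 22.6 CPM. The log2 fold change of cKO against WT was -0.41 ± 0.16 (SE) at cage activity (6 against 7 libraries, adjusted p = 1), -0.32 ± 0.17 in runners (6 against 6, adjusted p = 0.464) and -0.36 ± 0.12 for the mean of both (adjusted p = 0.981). Prkaa1 therefore did not pass the test adjusted over all genes. Its fold change for the mean of both was negative in all 43 alternative fits. Prkaa2 (ENSMUSG00000028518), which encodes the other catalytic subunit, had log2 fold changes of 0.04 ± 0.32 at cage activity and -0.58 ± 0.33 in runners (adjusted p = 1 and 0.482). Which exons the knock-out removes is not stated, and a count over the whole gene can include transcripts that lack them.

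Counts of Cre, the recombinase that deletes a floxed gene, were 0 in all 13 libraries labelled WT and 7 to 42 in 11 of the 12 labelled cKO. The library labelled cKO cage female replicate 3 had 0 Cre counts, which allows up to 0.122 CPM, under the lowest level of the other cKO libraries (0.269 CPM). Its Prkaa1 level, 17.6 CPM, lay within the range of the other cKO libraries and within that of the WT libraries (13.4 to 31.1 CPM). Counts of eGFP, a fluorescent reporter, stood at 84.3 to 264 CPM in 9 libraries and at no more than 2.6 CPM in the other 16, which are written as without eGFP. Of those 16, cKO cage female replicate 2 and cKO cage male replicates 2 and 3 had 64, 45 and 25 eGFP counts, and the other 13 had at most 1. The 9 were all 6 libraries labelled cKO running, cKO cage female replicate 1, cKO cage male replicate 1 and the library labelled WT running male replicate 2, which had 119 CPM and no Cre. Carriage of eGFP therefore differed between the groups, at 0 of 7 WT cage, 1 of 6 WT running, 2 of 6 cKO cage and 6 of 6 cKO running libraries. Scx (ENSMUSG00000034161, chromosome 15, 76457452 to 76459458), a transcription factor of tendon cells, stood at 105 to 207 CPM in the 9 libraries with eGFP and at 11.5 to 41.0 CPM in the other 16. Bop1 (ENSMUSG00000022557, chromosome 15, 76452989 to 76477277), a ribosome biogenesis factor on the opposite strand, stood at 152 to 563 CPM in the 9 and at 8.51 to 22.6 CPM in the other 16. The annotation places Scx inside Bop1, within intron 3 of 1 of its 4 transcripts.

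**Figure D1:**
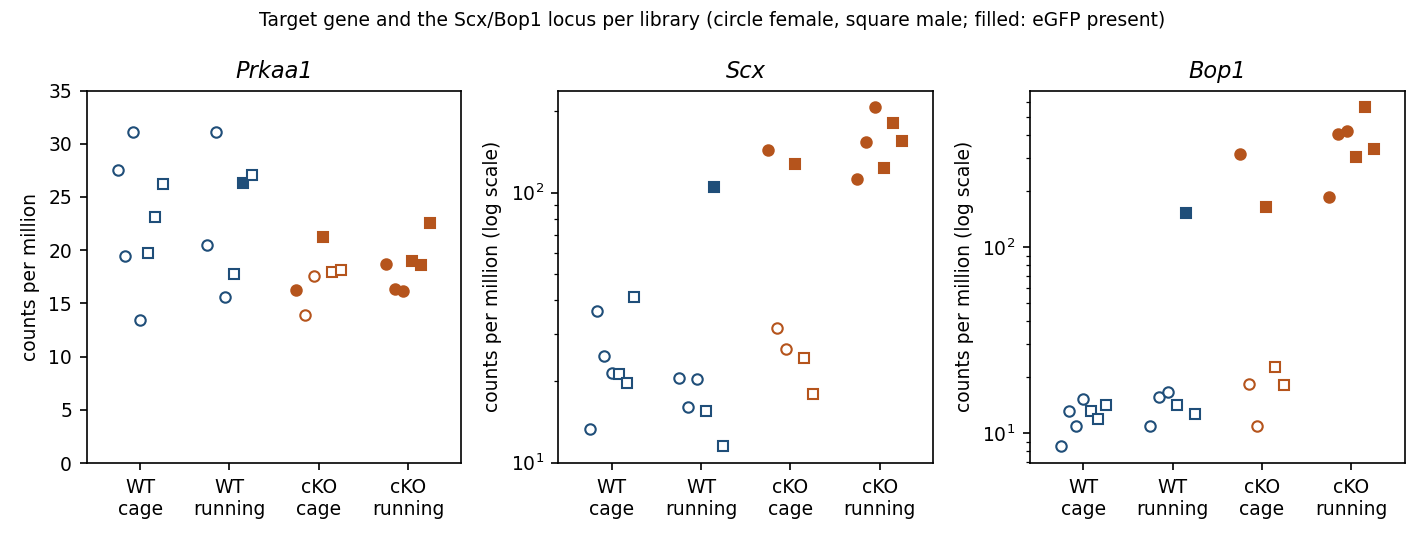
CPM of Prkaa1 (linear axis), Scx and Bop1 (log axes) in each of the 25 libraries, by genotype and activity, with circles for females, squares for males and filled symbols for libraries with more than 10 CPM of eGFP. The 9 filled symbols lie at 105 CPM or more for Scx and at 152 CPM or more for Bop1, the filled one labelled WT included, and the Prkaa1 values of the groups overlap.

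The tendon libraries also held RNA of skeletal muscle. Genes of muscle fibres took 14.7% ± 5.12 of the counts in WT cage (SD, n = 7), 16.0% ± 4.24 in WT running (n = 6), 14.2% ± 4.71 in cKO cage (n = 6) and 9.89% ± 3.54 in cKO running libraries (n = 6). The difference of -6.11 points between cKO and WT runners had an exact permutation p = 0.0281, and p = 0.113 after adjustment over the 4 comparisons made. The difference between cKO runners and cKO cage animals was -4.29 points (exact permutation p = 0.0974, adjusted p = 0.195), and the other 2 differences were 1.26 points between WT runners and WT cage animals and -0.567 points between the genotypes at cage activity (adjusted p = 0.839 for each by the exact permutation test). The 2 ribosomal RNA genes of mitochondria took 20.8% ± 4.61 of the counts in the 12 runners and 24.4% ± 3.86 in the 13 cage animals (SD, two-sided permutation p = 0.0425). That comparison was chosen after its values were seen.

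**Figure D2:**
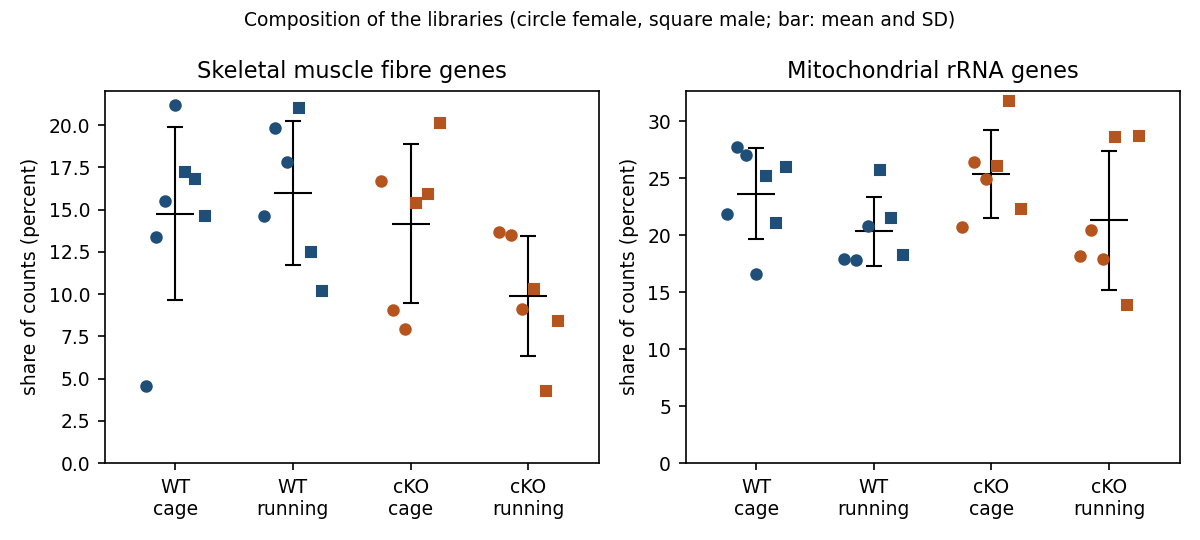
Share of each library's counts (percent) in skeletal muscle fibre genes and in mitochondrial rRNA genes, by genotype and activity, with circles for females, squares for males and bars for the mean and SD. The cKO running libraries have the lowest mean muscle share (9.89%), and WT cage female replicate 1 (4.57%) and cKO running male replicate 2 (4.25%) lie lowest of the 25.

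At cage activity, genes with the smallest p between cKO and WT tendons included Bop1 (log2 fold change 2.91 ± 0.70 SE), the histone gene H4c3 (0.71 ± 0.22) and Smpdl3a (0.36 ± 0.12) on the higher side, and Ccdc62 (-0.64 ± 0.21) and Zc2hc1c (-0.60 ± 0.20) on the lower side. None of them passed the test, with an adjusted p of 1 for each in 6 against 7 libraries, and Scx had 1.29 ± 0.49 (adjusted p = 1). Without the libraries with eGFP, Bop1 had 0.48 ± 0.18 and Scx -0.02 ± 0.25. Genes of fatty acid oxidation were higher as a list in cKO, 28 of 30 with a positive fold change and a median of 0.19 (camera adjusted p = 1.58e-05), and so were nuclear genes of oxidative phosphorylation, 69 of 76 positive with a median of 0.12 (camera adjusted p = 0.000308). Both calls were lost with an estimated correlation (adjusted p = 0.961 with an estimated correlation for each), and no member of either list passed when adjusted over the list alone. Macrophage genes (19 of 22 positive), interferon-stimulated genes (23 of 35) and endothelial genes (16 of 20) had camera adjusted p of 0.023, 0.023 and 0.0284 on the higher side, each with adjusted p = 0.961 with an estimated correlation. The tenocyte identity list (camera adjusted p = 0.942) and the list of AMPK subunits and upstream kinases (camera adjusted p = 0.788) did not pass. In edgeR 0 of the 19155 genes were called, and 217 had an unadjusted p under 0.05 where 958 would by chance. DESeq2 and limma-voom called 0 as well.

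In runners, the genes with the smallest p between cKO and WT were Bop1 (log2 fold change 3.42 ± 0.76 SE), Scx (2.36 ± 0.53) and Snx18, a sorting nexin (0.56 ± 0.13), on the higher side. On the lower side were the ubiquitin ligase gene Siah2 (-0.67 ± 0.16), the thyroid hormone receptor gene Thrb (-0.51 ± 0.13) and Hagh (-0.69 ± 0.18), which encodes a glyoxalase. None passed the test, with an adjusted p of 0.363 for each in 6 against 6 libraries. Gene lists moved together here. All 30 genes of fast muscle fibres had a negative fold change (median -0.71, camera adjusted p = 4.63e-10), as did all 15 of slow fibres (median -0.55, 1.85e-08), beside the lower muscle share of cKO runners. Nuclear genes of oxidative phosphorylation were lower in cKO, 73 of 76 negative with a median of -0.33 (camera adjusted p = 3.01e-15), and Cox5a had -0.74 ± 0.26 (adjusted p = 0.387). Higher in cKO were all 17 genes of Schwann cells and nerve (median 1.32, camera adjusted p = 3.26e-07), all 9 of mast cells (median 0.90, 0.000104), 38 of 44 fibrillar collagen and assembly genes (median 0.20, 0.00065) and 13 of 14 genes of mural and smooth muscle cells (median 0.30, 0.00065). Each of these calls had an adjusted p = 0.692 with an estimated correlation. With the muscle covariate, 7 lists were called by camera in this comparison in place of 17.

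Adjusted over the list alone, 4 Schwann cell genes, 4 mast cell genes and 4 mural genes passed in that comparison, among them the myelin enzyme gene Cnp (1.32 ± 0.36), the mast cell protease gene Cma1 (1.38 ± 0.50) and the contractile genes Acta2 (1.74 ± 0.54) and Tagln (1.66 ± 0.50). None of those passed over all genes, with adjusted p of 0.363 to 0.388. In edgeR 0 genes were called, and 2173 had an unadjusted p under 0.05 where 958 would by chance. DESeq2 and limma-voom called 0. Without the library labelled WT running male replicate 2, the only WT one with eGFP, 2 genes were called. With eGFP carriage as a covariate, which 6 of 6 cKO runners and 1 of 6 WT runners had, edgeR called 0 genes, 404 had an unadjusted p under 0.05, and Bop1 and Scx had log2 fold changes of 1.10 and 0.65.

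Averaged over both activities, Bop1 was the only gene of the 19155 called, and it was higher in the libraries labelled cKO (log2 fold change 3.17 ± 0.52, adjusted p = 0.0401). With eGFP carriage as a covariate, 0 genes were called. Scx had 1.82 ± 0.36 (adjusted p = 0.288). The Bop1 call held without cKO cage female replicates 1, 2 and 3 and cKO cage male replicates 2 and 3. The count was 2 without WT running male replicate 2 and 0 without any 1 of the other 19 libraries. DESeq2 called 2 genes, neither of them Bop1, and limma-voom 0, and 724 genes had an unadjusted p under 0.05.

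As the mean of both genotypes, runners differed from cage animals in 273 genes. Plekho1 (ENSMUSG00000015745), which encodes a casein kinase 2-interacting protein known from bone, rose by a log2 fold change of 1.01 ± 0.09 (SE, 12 against 13 libraries, adjusted p = 1.01e-06). It went from 19.5 ± 1.41 to 43.1 ± 9.74 CPM in WT (SD, n = 7 and 6) and from 19.2 ± 2.36 to 35.1 ± 6.47 CPM in cKO (n = 6 and 6), and each of the 12 runners lay above each of the 13 cage animals. The same separation held for Uchl1 (ENSMUSG00000029223), a ubiquitin hydrolase abundant in neurons (1.88 ± 0.20, adjusted p = 5.09e-06). Ndrg4 (1.32 ± 0.14, 5.09e-06), the cell cycle regulator gene Rgcc (1.25 ± 0.15, 4.96e-05), the cyclic nucleotide phosphodiesterase gene Pde10a (0.98 ± 0.12, 5.26e-05), the keratin gene Krt80 (0.91 ± 0.12, 0.000191), the heat shock gene Hspa1b (0.58 ± 0.09, 0.000682) and Agrp, a neuropeptide that blocks melanocortin receptors (2.92 ± 0.44, 0.00105), also rose. The water channel gene Aqp4 (ENSMUSG00000024411) fell the most clearly of the lower genes (-1.62 ± 0.19, adjusted p = 2.91e-05), from 19.8 ± 6.02 to 7.93 ± 5.06 CPM in WT and from 18.4 ± 6.74 to 5.27 ± 2.37 CPM in cKO. Tbc1d4, which controls glucose transporter traffic downstream of insulin and AMPK, fell (-0.85 ± 0.14, 0.00327), as did the deiminase gene Padi2 (-1.54 ± 0.26, 0.00357), Crim1 (-0.51 ± 0.09, 0.00357), the prenyltransferase gene Pggt1b (-0.38 ± 0.07, 0.00357) and Smc6, of a chromosome maintenance complex (-0.44 ± 0.08, 0.00377).

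**Figure D3:**
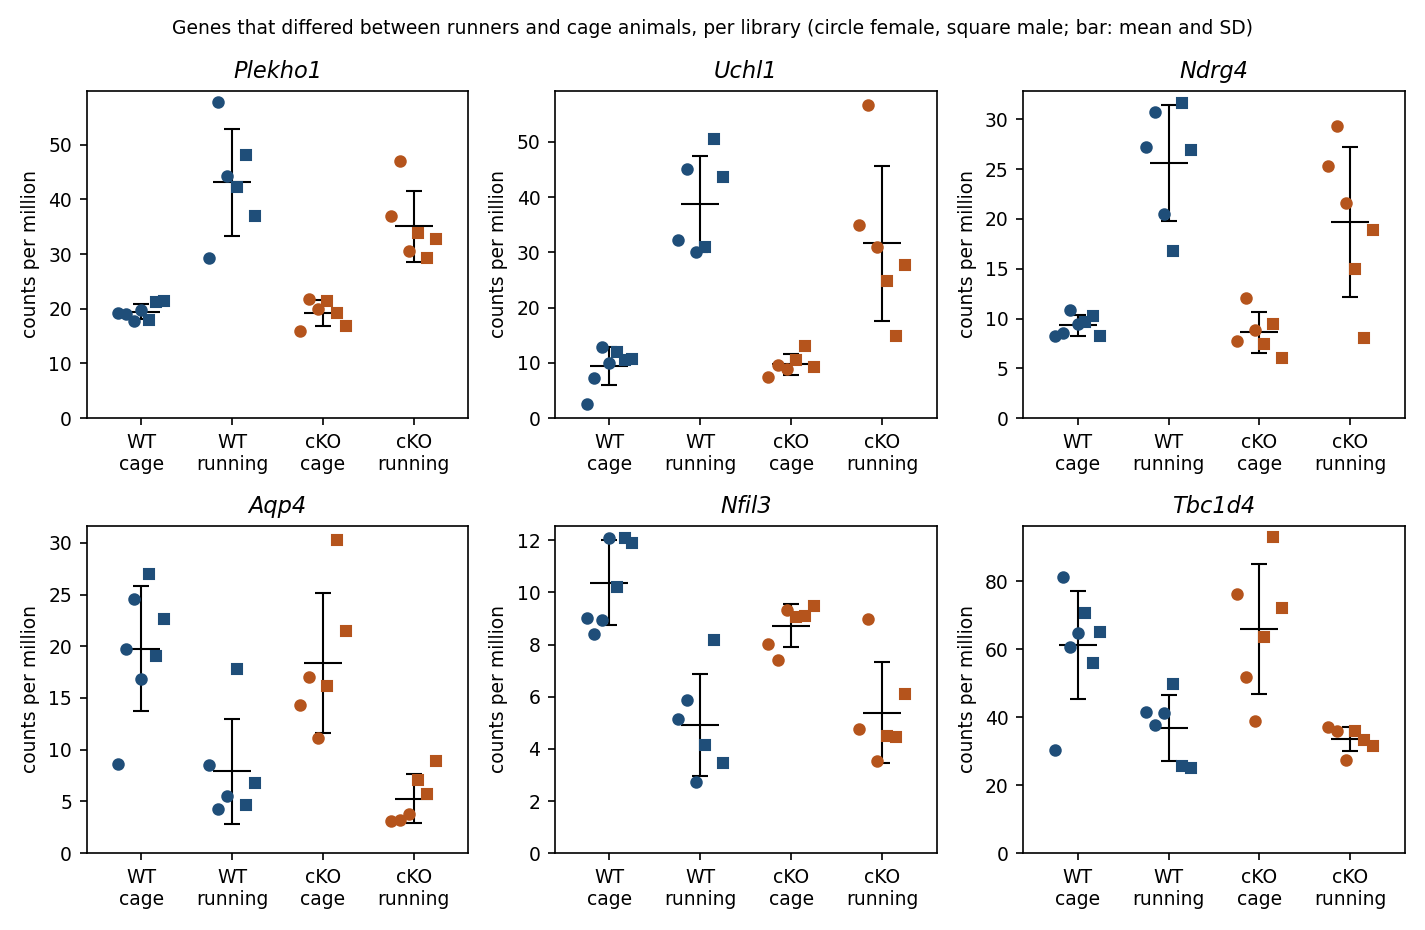
CPM of 6 genes in each library, by genotype and activity, with circles for females, squares for males and bars for the mean and SD. Plekho1, Uchl1 and Ndrg4 have higher means in the runners of both genotypes (Plekho1 43.1 and 35.1 against 19.5 and 19.2 CPM), and Aqp4, Nfil3 and Tbc1d4 have lower ones (Aqp4 7.93 and 5.27 against 19.8 and 18.4 CPM).

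Some genes of fatty acid oxidation fell in runners. Of 30 members, 29 had a negative fold change (median -0.44), 7 fell and 1 rose over all genes tested, and 22 fell and 1 rose when adjusted over the list alone. Acot2, a mitochondrial acyl-CoA thioesterase, fell by 0.93 on the log2 scale (SE 0.16, adjusted p = 0.00327), Decr1 by 0.54 (SE 0.10, 0.00645) and Eci1 by 0.59 (SE 0.13, 0.0149), and both of the latter encode enzymes for unsaturated fatty acids. The member that rose, Ucp2 (0.90 ± 0.16, 0.00488), encodes a mitochondrial carrier. The list had a camera adjusted p = 4.78e-17, but adjusted p = 0.652 with an estimated correlation, and a fry adjusted p of 0.0502. Of 24 genes of mitochondrial biogenesis and dynamics, 20 were negative and 1 fell, Ppargc1a, a coactivator that drives mitochondrial genes (-0.95 ± 0.19, 0.00988; list camera adjusted p = 0.000689). Nuclear genes of oxidative phosphorylation (71 of 76 negative, median -0.18, camera adjusted p = 3.33e-07) and the 13 mitochondrially encoded mRNAs (all negative, median -0.33, 8.74e-05) were lower as lists, with no member called over all genes or adjusted over the list alone. Neither was lower in WT alone by camera, where 48 of 76 were positive (median 0.05, adjusted p = 0.427) and 9 of 13 negative (0.532), and in cKO 74 of 76 and 13 of 13 were negative, beside a lower muscle share. With the muscle covariate the medians in cKO went from -0.39 to -0.16 and from -0.61 to -0.29 (camera adjusted p = 2.94e-11 and 1.75e-05), and without that covariate each had adjusted p = 0.54 with an estimated correlation in cKO. For the mean of both genotypes, biogenesis, oxidative phosphorylation and mitochondrial mRNAs had adjusted p = 0.652, 0.724 and 0.652 with an estimated correlation, in that order. The share of mitochondrial rRNA was lower in runners too, by 3.62 points. With that share as a covariate, Acot2, Ucp2 and Ppargc1a kept their calls, and Decr1 (-0.37, adjusted p = 0.0643) and Eci1 (-0.40, adjusted p = 0.16) did not.

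Single genes of matrix, lipid synthesis and clock lists were called in runners. Of 27 elastic fibre and matricellular genes, 2 rose, Ltbp2, a microfibril-associated protein (1.18 ± 0.22, adjusted p = 0.00616), and the proteoglycan gene Vcan (0.67 ± 0.18, 0.0498). When adjusted over the list alone, 9 were higher and 1 lower (camera adjusted p = 0.00087, adjusted p = 0.652 with an estimated correlation). The Vcan call held without 6 of the 25 libraries left out in turn. With the mitochondrial rRNA covariate, the Ltbp2 fold change was 0.90 (adjusted p = 0.123). Of 22 tenocyte identity genes, Cilp, a matrix protein of cartilage and tendon, rose (0.70 ± 0.15, 0.0142), and the list did not pass (camera adjusted p = 0.996). Fibrillar collagens and their assembly did not pass either (camera adjusted p = 0.185), with 0 of 44 called. In cholesterol synthesis, Srebf2, the transcription factor of the pathway, rose (0.45 ± 0.09, 0.00649), as did the enzyme gene Fdps (0.36 ± 0.09, 0.033), and 18 of 24 were positive (camera adjusted p = 0.00139, adjusted p = 0.652 with an estimated correlation). The Fdps call held in 15 of the 25 fits without 1 library. Of 19 circadian clock genes, 2 rose and 2 fell. Dbp rose (0.68 ± 0.12, 0.00377), the repressor gene Nfil3 fell (-0.88 ± 0.15, 0.00357), Clock fell (-0.35 ± 0.07, 0.0144) and Nr1d1, chosen after its values were seen, rose (0.35 ± 0.09, 0.0498). Camera did not call that list (adjusted p = 0.359), and the mixed form of fry did (adjusted p = 0.000458). Vcan, Cilp, Srebf2, Fdps and Clock also lost their calls with the mitochondrial rRNA covariate (adjusted p = 0.316, 0.0542, 0.0702, 0.107 and 0.107). Dbp and Nfil3 kept theirs (0.0287 and 0.0155).

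Lists of other cells also differed as the mean of both genotypes. Macrophage genes were higher in each genotype and as the mean, 21 of 22 positive with a median of 0.48 (camera adjusted p = 3.33e-07), with none called over all genes and 4 adjusted over the list alone, among them the lysosomal marker Cd68 (0.84 ± 0.24, adjusted p = 0.0783). Genes of synovial and sheath fibroblasts were higher (16 of 18 positive, camera adjusted p = 0.000681), and Pi16 (0.81 ± 0.18, 0.0233) and Tspan15 (0.51 ± 0.12, 0.0328) rose. The Tspan15 call held in 15 of the 25 fits without 1 library. Neither gene kept its call with the mitochondrial rRNA covariate (adjusted p = 0.219 for Pi16 and 0.19 for Tspan15). All 17 Schwann cell and nerve genes were positive (median 0.64, camera adjusted p = 0.000284) with 0 called, but in WT alone 11 of 17 were (median 0.07, adjusted p = 0.993). Each of these 3 lists had an adjusted p = 0.652 with an estimated correlation. Fast muscle fibre genes were lower, 23 of 30 negative with a median of -0.15 (camera adjusted p = 0.0255, adjusted p = 0.835 with an estimated correlation), but in WT alone 25 of 30 were positive (median 0.23, adjusted p = 0.211) and in cKO 29 of 30 negative.

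In total 117 genes rose and 156 fell in edgeR, 273 of 19155, where DESeq2 called 632 and limma-voom 912. The 8 higher and 8 lower genes named first for this comparison, with Acot2 and Nfil3 among them, were called in each of the 25 fits without 1 library. The total was 568 without WT cage female replicate 1, 159 and 169 without WT cage female replicate 2 and WT cage male replicate 1, and 127 without WT running male replicate 2. It was 171, 165, 144 and 148 without cKO cage female replicate 1 and cKO cage male replicates 1, 2 and 3, and 129 without cKO running female replicate 4. It was 619 with the muscle covariate, of which 271 were among the 273. With the mitochondrial rRNA share as a covariate it was 61, of which 57 were, and with eGFP carriage 11.

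Within WT, running raised 20 genes and lowered 5. Plekho1 (1.15 ± 0.13, adjusted p = 5.48e-05), Ndrg4 (1.48 ± 0.20, 0.00038), Uchl1 (2.05 ± 0.28, 0.00038), Pde10a (1.17 ± 0.17, 0.0011), Krt80 (1.06 ± 0.17, 0.00461), Fam214b (0.88 ± 0.14, 0.00461), Rgcc (1.28 ± 0.21, 0.00554) and the muscle kinase gene Sbk3 (2.67 ± 0.45, 0.00554) led the higher genes (6 against 7 libraries). Prpf4b, a kinase of the splicing machinery, was the first of the lower ones (-0.58 ± 0.10, 0.0102), and these 9 genes were called in each of the 25 fits without 1 library. Aqp4 (-1.39 ± 0.27, 0.025), Nfil3 (-1.07 ± 0.21, 0.0292) and the collagen receptor gene Itga1 (-0.45 ± 0.09, 0.0417) fell, with calls in 17, 16 and 6 of those 25 fits. Of 15 slow muscle fibre genes 14 were positive, and Csrp3, a muscle LIM protein, rose (1.61 ± 0.33, 0.0402, called in 7 of the 25 fits). That list had a camera adjusted p = 0.000242 and adjusted p = 0.954 with an estimated correlation. Macrophage genes were higher (20 of 22 positive, camera adjusted p = 0.000101), and fatty acid oxidation genes were lower (25 of 30 negative, 0.012), with Ucp2 again higher (1.23 ± 0.23, 0.0159). With an estimated correlation these had adjusted p = 0.954 and 0.995. DESeq2 called 161 genes and limma-voom 90. The count of 25 was 11 without WT running male replicate 2, 12 and 13 without WT cage female replicates 2 and 4, 15 and 14 without WT cage male replicates 1 and 3, and 39 without cKO running male replicate 2.

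Within cKO, running raised 6 genes and lowered 2. Plekho1 (0.87 ± 0.14, adjusted p = 0.00558), Uchl1 (1.70 ± 0.29, 0.0182), Ndrg4 (1.17 ± 0.21, 0.0226), Rgcc (1.22 ± 0.22, 0.0339) and Wdr78, of the motile cilium (1.44 ± 0.27, 0.0339), rose, and Aqp4 (-1.84 ± 0.28, 0.00558) and Decr1 (-0.79 ± 0.15, 0.0339) fell (6 against 6 libraries). Plekho1 and Aqp4 were called in each of the 25 fits without 1 library, and Uchl1, Ndrg4, Rgcc, Wdr78 and Decr1 in 20, 17, 15, 15 and 11 of them. Fatty acid oxidation genes were lower as a list, 28 of 30 negative with a median of -0.62 (camera adjusted p = 3.05e-22), and 25 fell and 1 rose when adjusted over the list alone. Oxidative phosphorylation genes followed, 74 of 76 negative with a median of -0.39 (1.54e-19). All 17 Schwann cell and nerve genes were positive (median 1.31, 4.14e-09), 9 of them passing adjusted over the list alone, and 29 of 30 fast muscle fibre genes were negative (median -0.51, 1.69e-07). With an estimated correlation the 4 lists had adjusted p = 0.507, 0.54, 0.54 and 0.54. Here too 6 of 6 runners and 2 of 6 cage animals carried eGFP, and with eGFP carriage as a covariate 0 genes were called. The 8 genes kept their direction there, with a median ratio of 0.91 between the log2 fold changes and of 1.36 between their standard errors. DESeq2 called 215 genes and limma-voom 384.

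The count of 8 in cKO depended on single libraries of both genotypes. It was 60 without WT cage female replicate 1 and 18 without WT running male replicate 3. It was 3 without cKO cage female replicate 1 or 3 or cKO cage male replicate 1 or 3, 5 without cKO cage female replicate 2 or cKO running female replicate 4, and 4 without cKO running male replicate 3.

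All 25 genes called in WT runners had the same sign in cKO, and all 8 called in cKO had the same sign in WT. The 2 sets shared 5 genes that rose and 1 that fell, where independent calls would share 0.00626 and 0.000522. Both sets came from the same fit, with a shared estimate of each gene's spread, so the calls were not independent and these values may understate a chance overlap. Across all genes, which are not independent replicates, the running effects of the genotypes had r = 0.129 (jackknife SE over libraries 0.217) and rho = 0.119, and the genotype effects at cage activity and in runners had r = -0.0382 (SE 0.241) and rho = -0.154. The interaction tests whether the genotypes responded differently to running. Its smallest p values were for Thrb (-0.77 ± 0.17), Hagh (-0.85 ± 0.25) and Cox15, an assembly factor of cytochrome oxidase (-0.59 ± 0.17), on the lower side and for Efcc1 (1.60 ± 0.39), Fam13b (0.52 ± 0.13) and the spectrin gene Sptbn5 (2.75 ± 0.69) on the higher side, all with an adjusted p of 0.672. Oxidative phosphorylation genes (72 of 76 negative, median -0.46, camera adjusted p = 1.15e-16), fatty acid oxidation genes (27 of 30 negative, 3.1e-08), fast muscle fibre genes (29 of 30 negative, 3.1e-08) and Schwann cell genes (17 of 17 positive, 3.09e-07) differed as lists, each with adjusted p = 0.806 with an estimated correlation. In edgeR 0 genes were called, and 1377 had an unadjusted p under 0.05 where 958 would by chance. DESeq2 and limma-voom called 0.

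Male and female tendons differed in 118 genes, 61 higher and 57 lower in males (12 against 13 libraries). Ddx3y, Kdm5d, Uty and Eif2s3y of the Y chromosome averaged 62.7, 21.2, 25.3 and 25.9 CPM in males and no more than 0.0518 CPM in females, and Xist averaged 512 CPM in females and 0.267 CPM in males. The complement gene C7 was higher in males (log2 fold change 5.22 ± 0.26, adjusted p = 7.23e-14), at 195.5 ± 104 against 5.24 ± 2.67 CPM (SD), as were the kinase gene Stk32a (1.70 ± 0.19, 4.96e-06), Plcxd3 (2.43 ± 0.30, 1.66e-05) and Nrep (0.87 ± 0.12, 9.2e-05). The neurotrophin receptor gene Ngfr (-2.09 ± 0.26, 2.04e-05), Cyp2d22 (-0.70 ± 0.09, 6.35e-05), the growth factor binding protein gene Igfbp3 (-1.35 ± 0.19, 0.000129), Ddhd1 (-0.62 ± 0.10, 0.000587) and the X-linked genes Kdm5c (-0.55 ± 0.06, 7.15e-07), Kdm6a (-0.70 ± 0.07, 1.01e-06) and Eif2s3x (-0.66 ± 0.08, 3.39e-05) were lower in males. DESeq2 called 251 genes and limma-voom 442.

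Genes of cholesterol synthesis were lower in males, 23 of 24 negative with a median of -0.27. Fdps fell (-0.43 ± 0.09, adjusted p = 0.0112), and 10 passed adjusted over the list alone. The list passed camera (adjusted p = 4.22e-09) and fry (adjusted p = 0.0151), with adjusted p = 0.4 with an estimated correlation. Matrix genes were lower in males too. The tenocyte identity list (16 of 22 negative, camera adjusted p = 0.000561) included the matricellular gene Tnc (-0.82 ± 0.19, 0.0364), the collagen list (36 of 44 negative, 0.00426) Col14a1 (-0.74 ± 0.15, 0.00915), and the elastic fibre list (22 of 27 negative, 0.00102) Ltbp4 (-0.47 ± 0.09, 0.0104). Each of the 3 had adjusted p = 0.747 with an estimated correlation, and 6, 6 and 3 of their members were lower adjusted over the list alone. The Tnc call held in 10 of the 25 fits without 1 library, and those of Col14a1, Ltbp4 and Fdps in all 25. All 17 Schwann cell and nerve genes were negative (median -1.14, camera adjusted p = 4.22e-09, adjusted p = 0.662 with an estimated correlation), 11 passing adjusted over the list alone.

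The interactions of sex asked whether males and females differed in their response to genotype and to running. For genotype, 41 of 44 collagen genes (median -0.40, camera adjusted p = 5.72e-13) and all 31 proliferation genes (median -0.78, 2.98e-11) had a lower cKO effect in males, and 18 of 19 adipocyte genes had a higher one (median 0.70, 2.98e-11). With an estimated correlation each had adjusted p = 0.368. The smallest p values of single genes were for Olfm1 (-0.66 ± 0.16), Atp6ap2 (-0.78 ± 0.19) and Glis3 (-0.83 ± 0.21), all with an adjusted p of 1. For running, the 15 slow muscle fibre genes had a lower effect in males (median -1.06, camera adjusted p = 8.61e-13), and the 17 Schwann cell genes (median 1.88, 8.51e-13) and 18 of 19 adipocyte genes (median 1.03, 8.02e-09) had a higher one, each with adjusted p = 0.522 with an estimated correlation. Adjusted over the list alone, 11, 11 and 14 members of these passed. WT cage female replicate 1 and cKO running male replicate 2 hold the least muscle RNA (4.57% and 4.25%) and the most adipocyte RNA (0.91% and 1.1%). Without these libraries the slow fibre, Schwann cell and adipocyte medians were -0.73, 1.89 and 0.66, and with the muscle covariate -0.38, 1.44 and 0.52, where 666 genes had an unadjusted p under 0.05. For genotype, the adipocyte median was 0.36 without those libraries. Adora1, an adenosine receptor gene (1.62 ± 0.31), the complement gene C2 (1.88 ± 0.37) and the protease gene Adamts8 (-2.72 ± 0.55) had an adjusted p of 0.347. In edgeR 0 genes were called in either interaction, with 795 and 2336 at an unadjusted p under 0.05. DESeq2 called 1 and 24, and limma-voom 0 in each. For running, the count was 25 without cKO running female replicate 4 and 1 without WT cage female replicate 1.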

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

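The tests of reporter reads, of muscle RNA, eGFP carriage and the size of fold changes among the running genes, and of the library without Cre were chosen after the results were seen, and the predictions for calls with the mitochondrial rRNA share, picked after its values were seen, and for Prkaa1 against muscle RNA were written before their tests.

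Scx and Bop1 stood apart in 1 WT library. In WT running male replicate 2, Scx was at 105 CPM (11.5 to 20.5 in the other 5 of its group) and Bop1 at 152 CPM (10.9 to 16.6), and eGFP was at 119 CPM (0 to 0.0219 in the other 12 WT libraries). In the libraries labelled cKO, 8 of 12 had eGFP over 10 CPM and 11 of 12 had Cre counts, signals in entries that the comparisons of genes do not use.

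The first pattern weighed is the higher Scx and Bop1 in libraries labelled cKO. Loss of AMPK as the whole cause is argued against at cage activity, where without the libraries with eGFP the log2 fold change of Scx was -0.02 (-0.0212, SE 0.251) in place of 1.29, and that of Bop1 was 0.479 (SE 0.182) in place of 2.91. Reads from a reporter transgene went with the values, since the WT library with eGFP had 105 CPM of Scx against at most 41.0 in the other WT libraries, and 4 of 4 cKO libraries under 10 CPM of eGFP lay within the WT range for Scx, whereas 3 of 4 lay above it for Bop1 (18.2 to 22.6 against at most 16.6 CPM), and a candidate explanation is a transgene with eGFP and sequence of the Scx locus, which lies inside Bop1. The remaining 0.479 of Bop1 goes with the 3 of these 4 that had 25 to 64 eGFP counts, while the one with 0 had 10.9 CPM. The same 3 had 14 to 35 Cre counts, and the one with 0 eGFP counts had 0 Cre counts as well. Low reporter reads may add to the remainder but cannot be told apart here from what goes with Cre, loss of AMPK included. Neither was tested further. Open too is a part of AMPK in runners, where Scx had 0.65 and Bop1 1.1 with the eGFP covariate in place of 2.36 and 3.42.

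The second pattern is the set of genes called between runners and cage animals. Unequal muscle RNA as its whole cause is argued against, since 271 of the 273 genes called for the mean of both genotypes kept call and direction with the muscle covariate. That covariate follows the amount of muscle RNA only. Whether a call arose in tendon cells or in the muscle that the libraries hold was not tested. Carriage of eGFP (6 of 6 cKO runners, 2 of 6 cKO cage animals, 1 of 6 WT runners) ended many calls. With it as a covariate, 11 of the 273 and 0 of the 8 called in cKO kept their call as standard errors grew (median ratio 1.24 and 1.36). The fold changes argue against carriage as the whole cause, since their median ratios were 0.959 and 0.91. For the 273 the lowest ratio was 0.514. In WT, 14 of 25 kept their call without the libraries with eGFP and 11 without WT running male replicate 2 alone. The median ratio of fold changes was 0.96 in each. Those that kept their direction at over 2 SE from 0 were 269 of 273, 8 of 8 and 25 of 25 in both WT fits. These genes were picked in the same libraries for folds far from 0, so only a large loss of fold would miss that mark. For the mitochondrial rRNA share the planned test decided nothing, since 57 of 273 kept their call where fewer than 20% or more than 80% would have. The fold changes with that share as a covariate had a median ratio of 0.908 (1.11 between standard errors), which argues against the share as the whole cause. By the test chosen afterwards 273 of 273 kept their direction at over 2 SE from 0, a mark with the same limit. A part for carriage and for that share in the fold changes stays open. Running is the factor that the design names, and it was tested on these libraries alone.

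The third pattern is that Prkaa1 was lower in cKO libraries by less than 2-fold. The library labelled cKO that carries no Cre is argued against as the cause. The log2 fold change for the mean of both activities was -0.371 without it and -0.363 (SE 0.12) with it. As 1 of 12 cKO libraries it could hardly move that value, so the fit does not show which genotype it has. Transcripts from muscle RNA could not be decided on, since Prkaa1 and the muscle share had r = -0.00967 (permutation p = 0.976) and rho = -0.021 (p = 0.955) over the 12 cKO libraries, and r = 0.0333 without the 2 libraries farthest from the median share. A deletion in only some of the cells of the tendon may leave such a level, and so may transcripts that lack the deleted exons, neither of which was tested. The fold change was negative in all 43 fits of the mean of both activities and passed the adjusted threshold in none of them.

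Other libraries stood apart from the rest of their group by the gap test for a lone value. Over 120 groups of 30 measures, 16 were found where about 6 would be by chance. In WT cage female replicate 1, adipocyte genes took 0.91% of the counts (0.317 to 0.536 in the other 6), and Prkaa2 was at 26.9 CPM (94.3 to 114), Rgcc at 88 CPM (50.9 to 66.6) and Crim1 at 50.6 CPM (70.8 to 82.8). Adipocyte genes took 1.1% in cKO running male replicate 2 (0.351 to 0.567). In cKO running female replicate 3, Rgcc was at 227 CPM (99.9 to 133) and Padi2 at 27.4 CPM (6.47 to 8.87). In cKO running male replicate 1, Itga1 was at 88.9 CPM (59.7 to 69.5) and Crim1 at 71.4 CPM (46.7 to 53.9). In cKO cage male replicate 2, Decr1 was at 137 CPM (71.5 to 94.3) and Acot2 at 43.6 CPM (16 to 20.2). Aqp4 was at 17.8 CPM in WT running male replicate 1 (4.3 to 8.56), Wdr78 at 6.87 CPM in WT running female replicate 2 (2.55 to 3.96) and Agrp at 1.62 CPM in WT cage female replicate 3 (0.116 to 0.672).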

How the results depend on the processing

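The fits with eGFP or mitochondrial rRNA as a covariate, and those without the libraries with eGFP, the 2 whose reporter counts stand against their group or the 2 lowest in muscle RNA, were chosen after the data were seen. Of the values of the 85 named results under alternatives, 3122 kept direction and side of the threshold, 516 kept direction but lost the threshold, 13 passed it and 2 reversed. Of those of counts, shares and correlations, 717 stayed and 170 moved, 5 reversed, 4 lost and 1 passed the threshold. Plekho1, Uchl1, Ndrg4, Rgcc, Pde10a and Aqp4 were called for the mean running effect in all 43 fits. Where no cause is given, the cause was not tested. Depth limits what a count of 0 excludes: up to 3 counts, or 0.0656 to 0.227 CPM by library. Every limma-voom count used quality weights for the libraries, which changes method and weighting together. FPKM are not TMM-scaled, and with 0.1 added the median fold change of all genes was 0.15 for the mean running effect, 0.27 for running in cKO, 0.19 for genotype in runners and 0.28 for sex by running, so changes there are relative to it (0.11, 0.18, 0.12 and 0.18 with 1 added). The replicate numbers do not pair the samples: the 78 same-number pairs had a median r of -0.015 and 195 other pairs 0.0074.

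With no filter, where 42619 genes were tested, edgeR called 4, 282 and 91 genes for genotype at cage activity, in runners and as the mean, 197, 574 and 715 for running in WT, in cKO and as the mean, 65 for the interaction, 445 for sex, and 111 and 887 for sex by genotype and sex by running. For running in WT, in cKO and as the mean, DESeq2 called 161, 215 and 632, and limma-voom 90, 384 and 912. DESeq2 also called 2 for mean genotype, 251 for sex, and 1 and 24 for the sex interactions. Limma-voom called 0 for mean genotype and 442 for sex. On log2(FPKM + 1) limma called 5 for running in cKO, 155 for mean running, 41 for sex, 0 for mean genotype and 1 for genotype in runners. On log2(FPKM + 0.1) it called 14, 3 and 147 for the 3 running effects, 46 for sex and 0 for mean genotype. The muscle covariate gave 260, 32 and 619 for running, 262 for sex and 0 for mean genotype, and lists called were 7 for genotype in runners, running in cKO and the interaction and 6 for mean genotype. Without the other library project, which is fewer samples, running had 12, 3 and 127, and 3 lists were called for genotype at cage activity. The replicate block gave 3 for running in cKO, 158 for mean running, 77 for sex, 0 for mean genotype and 3 lists for genotype at cage activity. The 8 group means gave 19 for running in cKO. The groups compared alone gave 12 and 5 for running in WT and cKO. Females alone gave 1, 0 and 8 for running and males alone 3, 30 and 102, with 0 for mean genotype in either sex, in fewer samples.

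Without cKO cage female replicate 3 (no Cre) and WT running male replicate 2 (eGFP without Cre), running had 10, 4 and 135 genes and genotype 2 in runners and 2 as the mean. Without the 2 lowest in muscle RNA, running had 59, 19 and 440, mean genotype 0 and sex by running 1, and lists called were 11 for genotype at cage activity, 8 for running in WT, 7 for the interaction and 23 for sex by genotype. The eGFP covariate gave 16, 0 and 11 for running, 0 for mean genotype and 8 lists for mean genotype. The mitochondrial rRNA covariate gave 5 for running in cKO, 61 for mean running and 10 for sex by running, with 2, 13 and 8 lists for genotype at cage activity, running in WT and sex. Without the libraries with eGFP, running in WT had 15 genes and sex 29, and no cKO runner was left for the other running and genotype comparisons. With an estimated correlation 0 lists were called in all 10 comparisons. Fry called 0 in 9 of them and 2 for sex, cholesterol synthesis (adjusted p = 0.0151) and mTORC1 and insulin signalling (0.0285). Its mixed form called 1, 2 and 11 lists for running in WT, in cKO and as the mean, 11 for sex and 0 in the other 6. As a share of summed FPKM, the muscle difference between genotypes at cage activity turned to 0.111 points, and those of genotype in runners and of running in cKO were -2.3 and -1.33 points in place of -6.11 and -4.29. Scx at cage activity turned to -0.0601 with the eGFP covariate and to -0.0212 without the libraries with eGFP.

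With each library left out in turn, calls were 0 to 2 for genotype in runners and for mean genotype, 11 to 39, 3 to 60 and 127 to 568 for running in WT, in cKO and as the mean, and 0 to 25 for sex by running. For running in WT, calls were 39 without cKO running male replicate 2, 11 without WT running male replicate 2 and 12 to 15 without WT cage female replicates 2 and 4 or WT cage male replicates 1 and 3. In cKO they were 60 without WT cage female replicate 1, 18 without WT running male replicate 3 and 3 to 5 without cKO cage females 1 to 3, cKO cage males 1 and 3, cKO running female replicate 4 or cKO running male replicate 3. As the mean they were 568 without WT cage female replicate 1, and 127 to 171 without WT cage female replicate 2, WT cage male replicate 1, WT running male replicate 2, cKO cage female replicate 1, any of the 3 cKO cage males or cKO running female replicate 4. Sex by running had 25 without cKO running female replicate 4 and 1 without WT cage female replicate 1. Genotype had 2 in runners and 2 as the mean without WT running male replicate 2, and 0 as the mean in 19 of the 25 fits. Lists called were 1 (without WT cage female replicate 4) to 10 (without WT cage female replicate 1) for genotype at cage activity (3 without WT cage male replicate 1, 8 or 9 without cKO cage females 2 and 3 or cKO cage male 2), 2 (WT running female replicate 1) to 13 (WT cage female replicate 3) for running in WT (8 or 9 without WT cage female 1, WT running female 3 or WT running male 3), 7 (WT running male replicate 1 or cKO cage male replicate 2, with 9 without cKO running male replicate 3) to 20 (cKO running male replicate 2) for sex and 9 (WT running female replicate 3) to 19 for sex by genotype. The muscle share differences ranged from -2.26 to 0.681 points for genotype at cage activity, from -7.27 to -4.99 in runners, from -0.438 to 2.42 for running in WT and from -5.54 to -3.11 in cKO. The first turned positive without WT cage female replicate 4 and cKO cage female replicates 2 and 3, and the third negative without WT cage female replicate 1. In runners the exact permutation p was 0.05 or more without WT running female replicate 2 or 3, WT running male replicate 1 or cKO running male replicate 2, and in cKO it was lower than 0.05 without cKO cage female replicate 3.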

Other observations

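The splits of the samples were planned before the data were examined, and the look at what other splits with many calls have in common was chosen after they were seen.

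Stress- and oxygen-related lists were lower in runners. Of 16 glucocorticoid-responsive genes 14 had a negative fold change, and Pdk4, which blocks the entry of pyruvate into the mitochondrial cycle, fell (log2 fold change -1.44 ± 0.33 SE, adjusted p = 0.024, 12 against 13 libraries). The list had a camera adjusted p = 0.00423 and adjusted p = 0.652 with an estimated correlation, and with the mitochondrial rRNA covariate Pdk4 kept its direction (adjusted p = 0.261, at most 0.565 over its 43 fits). Of 24 hypoxia and angiogenesis genes 17 were negative, and Angpt1, a ligand that stabilises vessels, fell (-0.45 ± 0.09, 0.0101), whereas the glucose transporter gene Slc2a1 had 0.57 ± 0.16 (0.0649). That list had a camera adjusted p = 0.0264 and adjusted p = 0.652 with an estimated correlation. Angpt1 lost its call with the mitochondrial rRNA covariate (adjusted p = 0.105). Of 33 immediate early and load-responsive genes 23 were negative (camera adjusted p = 0.0294, adjusted p = 0.652 with an estimated correlation), none was called over all genes, and Junb (0.36 ± 0.11) and Zfp36 (-0.34 ± 0.10) passed in opposite directions when adjusted over the list alone. Neither of the latter lists was called by camera in WT or in cKO alone (adjusted p of 0.0642 to 0.221). All 8 keratinocyte and skin genes were positive as the mean (camera adjusted p = 0.0266, adjusted p = 0.652 with an estimated correlation), with Sbsn higher (0.89 ± 0.20, 0.0233), but 5 of 8 were negative in WT. With the mitochondrial rRNA covariate the Sbsn call was lost (adjusted p = 0.306). Krt14 and Krt5 were at 21 and 16.8 CPM in cKO running male replicate 2 and at no more than 1.53 and 0.196 CPM in the other 11 runners.

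Males had lower levels of further lists. Of 22 senescence and secretory genes 16 were negative, led by Igfbp3, with 4 lower adjusted over the list alone (camera adjusted p = 0.023, adjusted p = 0.634 with an estimated correlation). All 5 erythroid genes (median -1.14, camera adjusted p = 0.00583) and all 9 mast cell genes (median -0.69, 0.00583) were negative, each with adjusted p = 0.747 with an estimated correlation. Plat, a plasminogen activator, was lower (-0.52 ± 0.12, 0.0496), and Has2, which makes hyaluronan, was higher (0.76 ± 0.18, 0.0496), with calls in 6 of the 25 fits without 1 library for each. The transcription factor gene Atf5 was lower (-0.35 ± 0.07, 0.00968).

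Other splits of the same libraries were fitted to ask whether chance can give as many genes, by the number called and by the number at an unadjusted p under 0.05. By the number called, chance can be excluded for running in WT (25 genes, 1 of 93 splits, the real one, highest other 2). Few splits gave as many genes for running as the mean (273, 3 of 100), running in cKO (8, 2 of 76) and sex (118, 2 of 60), the real one counted. In each, though, the highest other split gave more than the real one (616, 90 and 179), so chance is made less likely there but is not excluded. For mean genotype the count was 1 gene, which 1 other split of 100 reached (2 with the real one, highest other 1), and which 19 of the 25 fits without 1 library lost. By the number at an unadjusted p under 0.05, the splits do not exclude chance for any of these counts. As many genes came in 6 of 93, 5 of 100, 5 of 76, 4 of 60 and 39 of 100 splits in that order. The splits weigh the number of genes and not single genes, such as the Y-linked ones between the sexes. None of these shares is adjusted over the comparisons. A count of 0 is matched by every split by construction, so the 95 of 95 for genotype at cage activity (highest other 0), 75 of 75 in runners (1), 100 of 100 for the interaction (26), 60 of 60 for sex by genotype (0) and 60 of 60 for sex by running (1) decide nothing. By the unadjusted p, chance cannot be excluded there either (84 of 95, 7 of 75, 11 of 100, 28 of 60 and 3 of 60).

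Splits that called many more genes than the real one point to a structure of the libraries. Those with 616 and 343 genes parted the libraries by 4.40 and 4.50 points of muscle share where the real split parts them by 1.55, and only 3 and 2 of the 100 splits parted them by as much. The split with 90 genes differed by 5.15 points (real 4.29) and that with 179 by 3.55 (real 0.287). For the interaction, though, the split with 26 genes (real 0) parted the libraries by 0.955 points, and 63 of 100 splits parted them by as much. What the structure is stays open.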
